A study of Mus musculus with 10 samples.

How the data were processed

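RNA from sorted mouse lung epithelial cells was measured on 10 Affymetrix expression arrays, 5 from each of 2 cell populations. Per the labels' protocols, 100 ng of total RNA from each sample was purified on silica columns, amplified linearly from poly(T)-primed cDNA and labelled with biotin. The deposited table holds log2 values of 41345 probe sets, already normalized by the authors. The submitters' processing notes name oligo, RMA and limma without versions and without saying what each was used for. RMA corrects background, equalizes the distributions of the arrays and summarizes the probes of each set, and the table looks like its output: array medians lay between 5.89 and 5.97 and the values ran from 1.69 to 14.16. The order of these steps and the log base were not given in the sources used here, and base 2 was taken from the range of the values. Such values understate the change of dim genes, because background signal adds to every probe. The number of arrays limits the precision.

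Gene names came from the platform's annotation table, which may be old. It paired 23521 probe sets with 1 gene symbol, 1814 with several and 16010 with none, and no gene was named from a probe set with several. Where 1 gene had more than 1 probe set, as 1082 genes did, the probe set with the highest mean over all arrays was used, which left 22180 genes. Gene order along chromosomes was taken from the RefSeq gene table of assembly GRCm38.p6. No coordinates are given, because the assembly behind the probe annotation was not given in the sources used here.

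Groups were taken from the sample titles. The replicate numbers run from 1 to 5 in both groups, but no label says that a number marks a shared litter, sort or array batch, or that replicates are separate animals. The p-values therefore measure the spread between these samples, part of which may be technical. No scan dates were used here, so array batches could not be examined.

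The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with statmod 1.5.0) on the deposited log2 values, without covariates. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences are Axin2+ minus SP-C+ on the log2 scale, with the moderated standard error (SE). Axin2 and Sftpc were also tested by an exact permutation test over all assignments of the arrays to the groups. Gene lists were tested with camera, which compares a list with all other genes, at a preset correlation between genes of 0.01. The adjustment ran over 23 lists, and sex-linked genes were a further list given per array only. Of the 655 gene names in the 24 lists, 605 matched a measured gene, 5 of them through a synonym. Some of these names were of the same gene. Camera with a correlation estimated from the data and fry, which asks whether the genes of a list move one way, were alternatives.

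The groups, tests, gene lists, alternative settings and the rule for naming genes were fixed before the data were examined. The rule names Axin2 and Sftpc; the 12 largest rises and the 12 largest falls among called genes whose groups did not overlap, leaving out predicted and unnamed genes; and the 2 largest called rises and falls of each list. Of the genes this rule names, 1 is not reported here, although it is kept in all counts. The alternative settings were the replicate number as a block, median centring, quantile normalization, 2 filters on dim genes (25th and 50th percentile), the mean over probe sets, an intensity trend with robust variances, array weights, leaving out each array, all probe sets, and stricter thresholds. Added after the data were seen were a covariate for Y-linked expression, leaving out SP-C+ replicates 4 and 5, leaving out SP-C+ replicates 1, 2 and 3, and the other Axin2 probe set.

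The fit was tested on simulated data for this comparison over 22180 genes, of which 200 were changed. It recovered 62% of genes changed by 0.5 on the log2 scale, 94% of those changed by 1 and 100% of those changed by 2 or 3, and 5.32% of its calls were false. A list shifted by 1 was called in the right direction, and 0 lists were called when nothing was changed. Probe sets with several symbols or none entered only a fit over all probe sets.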

Results

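Type 2 alveolar epithelial cells (AEC2s) make surfactant and renew the gas-exchange surface of the lung, where they give rise to the flat type 1 cells (AEC1s). Gene expression was measured in sorted cells labelled as AEC2s from mouse lungs at postnatal day 4, as 5 samples of each of 2 populations. SP-C+ cells carried YFP after 24 h of lineage tracing with a tamoxifen-dependent Cre driven by Sftpc, the surfactant protein C gene. Axin2+ cells carried a label of tamoxifen-dependent Cre and TdTomato driven by Axin2. Their sort also required the epithelial protein EpCAM and excluded CD31, an endothelial protein, and CD45, a leukocyte protein. The gate given for Axin2+ cells named no AEC2 marker. Axin2 is a target and feedback inhibitor of canonical Wnt signalling. The comparison therefore sets cells labelled as Wnt-responsive AEC2s against cells labelled as AEC2s as a whole. All mice had a mixed C57BL/6, 129S6 and CD-1 background. A shared description of the samples mentions postnatal day 3 and adult cells, but the titles and age labels of all 10 say day 4. Each population came from a mouse line, reporter and gate of its own, so these cannot be separated from the cell labels.

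AEC1 and ciliated cell marker genes were far higher in arrays labelled Axin2+ than in SP-C+ arrays, with 24 of 25 AEC1 markers and 25 of 26 ciliated cell markers higher. Smaller rises were found among cell cycle genes (34 of 47) and Hippo and YAP genes (13 of 17). Small falls were found among AEC2 markers (9 of 30) and lipid synthesis genes (17 of 32). Of these 4 lists only Hippo and YAP genes kept their call with an estimated correlation. Without SP-C+ replicates 1, 2 and 3 only 13 cell cycle and 4 lipid synthesis genes passed in these directions. Spock2, a secreted proteoglycan gene of the AEC1 list, was 23.2-fold higher in Axin2+ arrays (log2 difference 4.54 ± 0.11 SE, n = 5 per group, adjusted p = 1.71e-10 in limma). Cdhr3, a cadherin-related gene of ciliated airway cells, was 20.6-fold higher (4.36 ± 0.17, adjusted p = 1.89e-09). The steepest falls were smaller, with Npffr2, which encodes a neuropeptide FF receptor, 5.19-fold lower (-2.38 ± 0.25, adjusted p = 1.93e-05), and Axin2 itself was lower.

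Of 22180 genes, 3894 (17.6%) passed the threshold, 1909 higher and 1985 lower in Axin2+ arrays, and 322 of these were predicted or unnamed genes. Large differences ran mostly one way. At least 2-fold differences were found for 640 called genes that were higher and 75 that were lower, and at least 8-fold differences for 60 and 0. In 3334 genes (15.0%) the groups did not overlap, against 0.794% by chance. The first principal component held 56.4% of the variance and separated the groups, and arrays correlated at 0.987 to 0.993 within SP-C+, 0.993 to 0.995 within Axin2+ and 0.973 to 0.983 between them.

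The driver genes of both labels were examined first. Axin2 measured 7.93 ± 0.12 (SD, n = 5) in arrays labelled Axin2+ and 8.46 ± 0.06 in SP-C+ arrays, a difference of -0.53 ± 0.08 SE (adjusted p = 3.28e-04 in limma). The groups did not overlap, and the exact permutation p was 0.00794, the smallest that the possible assignments of these arrays allow. The other Axin2 probe set gave 6.01 ± 0.09 and 6.33 ± 0.17, a difference of -0.32 with an adjusted p of 0.0557 over all probe sets (exact permutation p = 0.00794). The position of either probe set relative to the Axin2-driven Cre was not given in the sources used here, so Axin2 cannot check the label, and Axin2+ is used here as a label only. Sftpc measured 14.11 ± 0.03 in Axin2+ and 14.02 ± 0.03 in SP-C+ arrays, a difference of 0.10 that did not pass limma's threshold (adjusted p = 0.324) although the groups did not overlap (exact permutation p = 0.00794). It was the brightest of all genes, near the highest value on any array, 14.16.

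**Figure D1:**
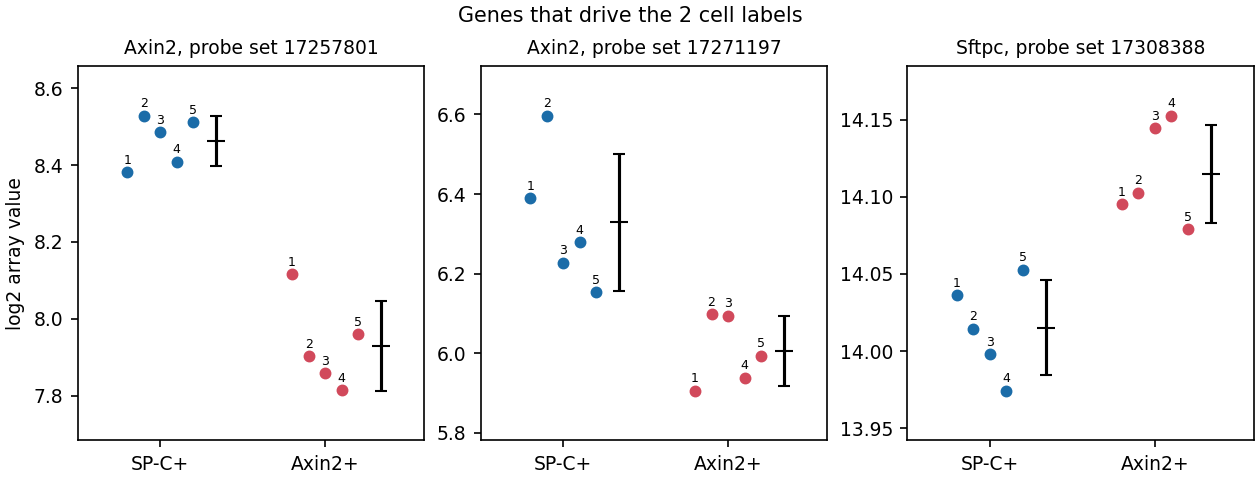
Log2 values of both Axin2 probe sets and of Sftpc in each array, numbered by replicate, for SP-C+ (blue) and Axin2+ (red); black bars are the mean ± SD of 5 arrays. Axin2 lies lower in all 5 Axin2+ arrays in both probe sets (difference -0.53 and -0.32), and Sftpc differs by 0.10.

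AEC1 markers rose almost as a whole. Of 25 measured, 24 were higher in Axin2+ arrays and 0 lower, and all 25 were higher when adjusted over the list alone. The list median was 2.27 and its camera adjusted p was 1.31e-37 (adjusted p = 0.0265 with an estimated correlation). Sema3e, which encodes a secreted semaphorin, rose by 4.20 ± 0.22, beside Spock2. In SP-C+ arrays 24 of the 25 genes already lay above the array's median gene. Further genes among the 12 with the largest rises were P4ha3, a prolyl hydroxylase subunit (4.29 ± 0.22), Rasgrf2, an exchange factor for Ras (4.23 ± 0.14), Pxdn, the collagen IV crosslinking enzyme peroxidasin (4.20 ± 0.22), Cyp2s1, a cytochrome P450 (4.14 ± 0.11), and Scel, sciellin of the cornified envelope (4.09 ± 0.12). All of these had adjusted p-values of 3.56e-08 or lower.

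Genes of multiciliated cells were also strongly raised. Of 26 ciliated cell markers 25 rose and 0 fell, with the same counts adjusted over the list alone, a median of 2.16 and an adjusted p of 4.39e-48 (adjusted p = 0.00406 with an estimated correlation). Fam183b, a gene of motile cilia, rose by 4.35 ± 0.10, and Sntn, which encodes a protein of the ciliary tip, by 4.07 ± 0.12. Spata18, a mitochondrial quality control gene outside the list, rose by 3.94 ± 0.12. In SP-C+ arrays only 5 of the 26 lay above the array's median gene, and the list mean was 5.56 ± 0.07 (SD, n = 5) against 8.02 ± 0.14 in Axin2+ arrays.

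Club and secretory cell markers rose in part, with 9 of 19 higher and 0 lower. Adjusted over the list alone 10 were higher and 1 lower, the median was 0.64 and the adjusted p 6.81e-06 (adjusted p = 0.0265 with an estimated correlation). Scgb1a1, the club cell secretoglobin, rose by 2.73 ± 0.29 to 13.00 ± 0.16 (SD), and Aldh1a1, a retinaldehyde dehydrogenase, by 2.68 ± 0.12. The median was 0.42 without Axin2+ replicate 5, and the count was 5 of 9 among genes above the 50th percentile. Among 13 basal and neuroendocrine markers 5 were higher and 0 lower, also adjusted over the list alone, with Pcsk1, a prohormone convertase, at 0.81 ± 0.12 and Ddc, the aromatic amino acid decarboxylase, at 0.66 ± 0.13. This list passed at an adjusted p of 0.0412 with a median of 0.02, but not with an estimated correlation (adjusted p = 0.155), and its adjusted p reached 0.0791 without SP-C+ replicate 4, 0.0762 without Axin2+ replicate 2 and 0.0643 without SP-C+ replicate 1. It also did not pass with quantile normalization, array weights, the mean over probe sets or either filter on dim genes, or without SP-C+ replicates 4 and 5 (adjusted p = 0.0522 to 0.177).

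**Figure D2:**
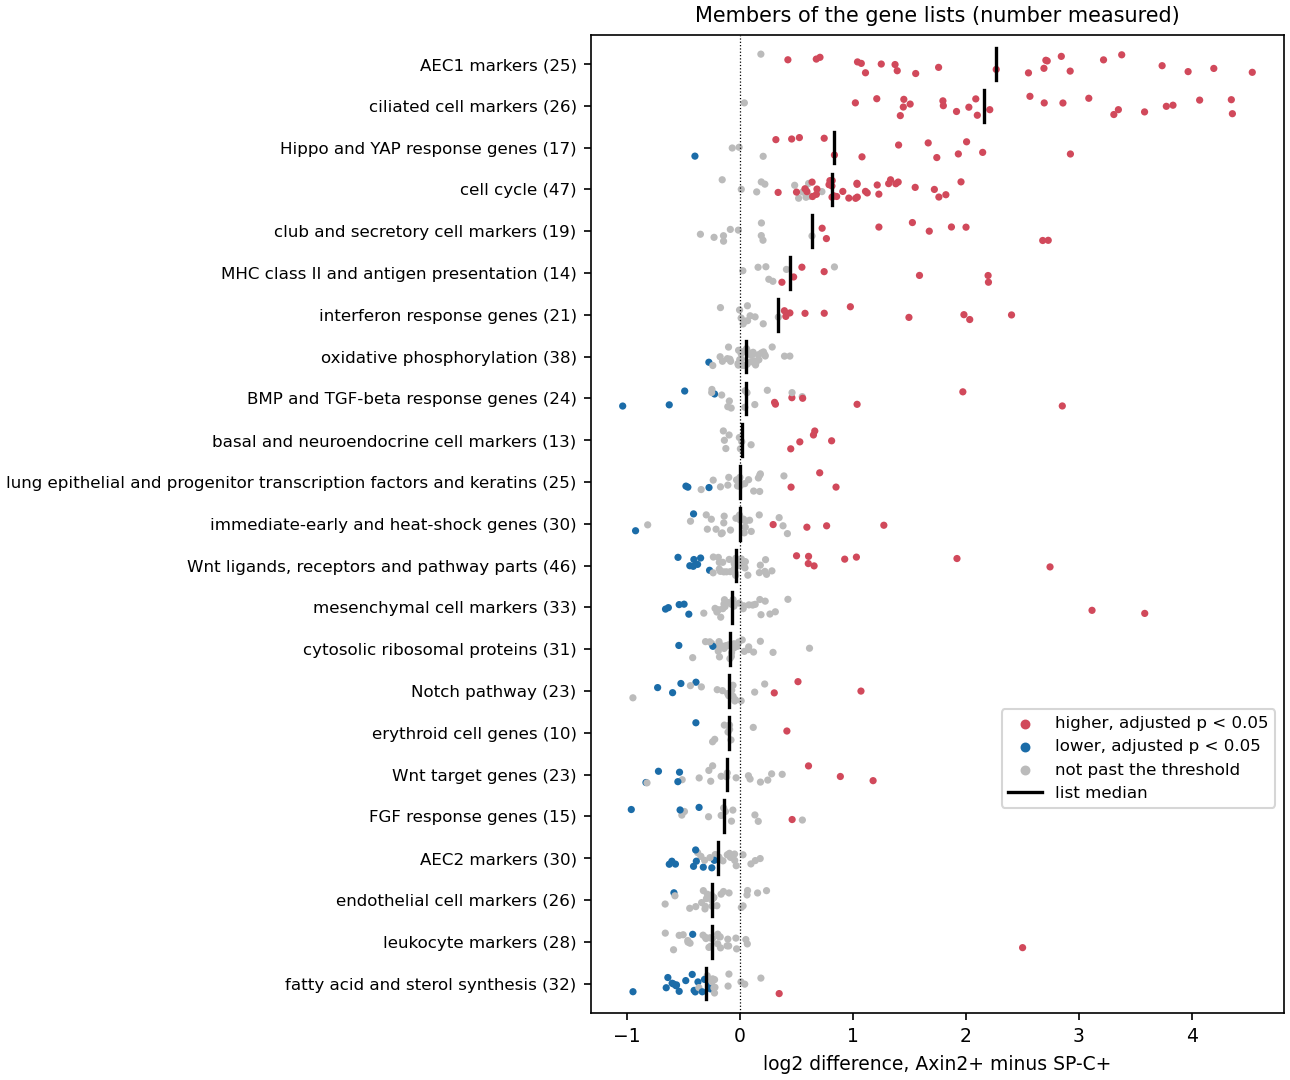
Log2 difference, Axin2+ minus SP-C+, of each measured member of 23 gene lists, 1 point per gene; red and blue mark genes that passed the threshold, grey those that did not, and black bars are list medians. AEC1 (median 2.27) and ciliated cell markers (2.16) stand farthest to the right, and fatty acid and sterol synthesis genes (-0.30) farthest to the left.

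AEC2 markers fell slightly. All 30 lay above the median gene in SP-C+ arrays. Of these, 9 were lower and 0 higher in Axin2+ arrays, with 12 lower adjusted over the list alone, at a median of -0.19. Cebpa, a transcription factor of AEC2 maturation, fell by 0.62 (SE 0.07, adjusted p = 3.81e-05). Acoxl, an acyl-CoA oxidase-like gene, fell by 0.60 (SE 0.16, adjusted p = 0.0198). The list's adjusted p was 9.13e-04, and the call was lost with an estimated correlation (adjusted p = 0.369). The count of lower genes was 5 without SP-C+ replicates 4 and 5 and 5 with Y-linked expression as a covariate, and Acoxl did not pass without SP-C+ replicates 4 and 5 (adjusted p = 0.106) or without Axin2+ replicate 1 (adjusted p = 0.0517).

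Fatty acid and sterol synthesis genes, which supply surfactant lipids, also fell. Of 32 measured 17 were lower, and 24 were lower adjusted over the list alone, with a list median of -0.30. Acss2, which makes acetyl-CoA from acetate, was lower by -0.94 ± 0.25, and Cyp51, the sterol demethylase, by -0.65 ± 0.14. Ebp, a sterol isomerase, was the 1 member higher (0.35 ± 0.10; adjusted p = 0.0539 without Axin2+ replicate 3). The list passed at 1.59e-06 after adjustment, but not with an estimated correlation (adjusted p = 0.185). The number of lower genes depended on which SP-C+ arrays were used: 4 without replicates 1, 2 and 3, where Acss2 and Cyp51 were at -0.22 ± 0.10 and -0.30 ± 0.10 and did not pass (adjusted p = 0.176 and 0.0821), and 19 without replicates 4 and 5. It was 11 without Axin2+ replicate 3 and 11 with the Y-linked covariate, where Acss2 was at -0.83 ± 0.26, a slightly smaller difference with a similar SE, and did not pass (adjusted p = 0.0565).

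The 12 genes with the largest falls, Npffr2 among them, also held metabolic genes. Fbp2 and Fbp1, the fructose bisphosphatases of gluconeogenesis, were lower by -2.14 ± 0.23 and -1.83 ± 0.25. Transporter and channel genes were among them: Slc10a6, which takes up sulfated steroids (-1.96 ± 0.20), Slc35g1 (-1.45 ± 0.14), the connexin gene Gjb6 (-1.49 ± 0.15) and Atp6v0a4, a proton pump subunit (-1.44 ± 0.30). The rest were Gdpd2, a glycerophosphodiesterase (-1.78 ± 0.27), Ivl, involucrin (-1.74 ± 0.29), Vnn3, a pantetheinase (-1.70 ± 0.24), Fcamr, an Fc receptor for IgA and IgM (-1.52 ± 0.25), and H2-Ea, described with the MHC genes. Adjusted p-values of these 12 were 0.00505 or lower.

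Cell cycle genes were higher in the same arrays as AEC1 (median 2.27) and ciliated cell markers (2.16). Of 47 measured, 34 rose and 0 fell, with 39 higher adjusted over the list alone and a median of 0.82. Cdk1, the mitotic kinase, rose by 1.96 ± 0.46 and Mcm5, a subunit of the replicative helicase, by 1.83 ± 0.32. The adjusted p was 1.41e-19 with the preset correlation, but the call was lost with one estimated from the data (adjusted p = 0.218 with an estimated correlation). The list varied within both groups. Its mean was 6.44, 6.47 and 6.50 in SP-C+ replicates 1, 2 and 3, against 7.05 and 7.23 in replicates 4 and 5, and lay between 7.14 and 7.98 in Axin2+ arrays. Without SP-C+ replicates 1, 2 and 3, 13 of the 47 genes passed (median 0.45), and Cdk1 did not (0.84, adjusted p = 0.238). Without replicates 4 and 5, 41 passed (median 1.06).

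**Figure D3:**
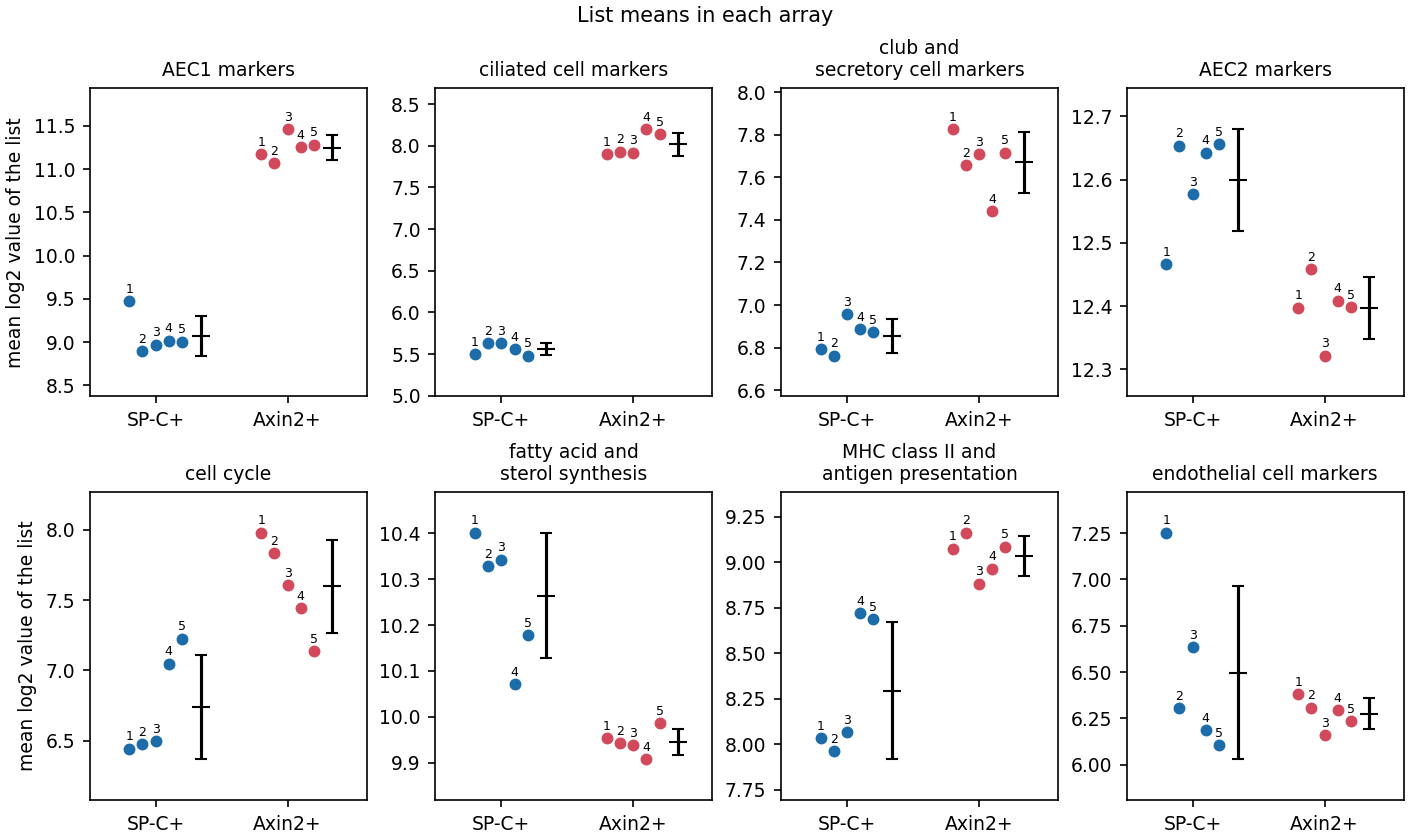
Mean log2 value of 8 gene lists in each array, numbered by replicate, for SP-C+ (blue) and Axin2+ (red); black bars are the mean ± SD of 5 arrays, and each panel has its own axis. AEC1 means lie between 8.90 and 9.47 in SP-C+ arrays and between 11.06 and 11.46 in Axin2+ arrays, while cell cycle means of SP-C+ replicate 5 (7.23) and Axin2+ replicate 5 (7.14) overlap.

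Wnt target genes did not shift as a list. Of 23 measured, 3 were higher, 4 lower and 16 did not pass; adjusted over the list alone 4 were higher and 4 lower. The median was -0.12 and the adjusted p 0.723 (adjusted p = 0.804 with an estimated correlation). Wif1, a secreted Wnt inhibitor, rose by 1.18 ± 0.10, and Ccnd1, cyclin D1, by 0.89 ± 0.21. Nkd1, an intracellular Wnt antagonist, was lower by -0.83 ± 0.15 and Myc by -0.72 ± 0.16. Ccnd1 and Myc did not pass without SP-C+ replicates 1, 2 and 3 (adjusted p = 0.121 and 0.186).

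Wnt ligands, receptors and pathway parts also moved both ways. Of 46 measured, 8 were higher and 7 lower, or 10 and 8 adjusted over the list alone. The ligand genes Wnt3a and Wnt7a rose by 2.75 ± 0.16 and 1.92 ± 0.19. The receptor genes Fzd8 and Lgr4 were lower by -0.55 ± 0.12 and -0.44 ± 0.08, and Fzd8 did not pass without SP-C+ replicates 1, 2 and 3 (adjusted p = 0.134), where 3 members were lower. The list had a median of -0.03 and a mean of 0.12, so these differ in sign, and camera found no shift (adjusted p = 0.431, direction up). Fry, which weighs members in 1 direction without other genes as background, passed (adjusted p = 0.0171).

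Among other lists, Hippo and YAP response genes rose in the same arrays as AEC1 (median 2.27) and ciliated cell markers (2.16), with 13 of 17 higher and 1 lower (14 and 1 adjusted over the list alone). Their median was 0.84 and the adjusted p 1.50e-12 (adjusted p = 0.0265 with an estimated correlation). Ccn2, a matricellular YAP target, rose by 2.93 ± 0.16 and Ankrd1 by 2.15 ± 0.16. The list also holds pathway genes such as Yap1, Tead1 and Lats2, so it does not measure response alone. Nuak2 was lower by -0.40 ± 0.13, a call that ended in 7 of the 10 fits without 1 array (adjusted p up to 0.122, without Axin2+ replicate 3).

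BMP and TGF-beta response genes split, with 7 of 24 higher and 4 lower (10 and 4 adjusted over the list alone). The list also holds ligand and receptor genes. Tgfb2 rose by 2.86 ± 0.21 and the signal transducer Smad9 by 1.98 ± 0.21, while the ligand gene Bmp2 was lower by -1.04 ± 0.19 and Bambi, a decoy receptor gene, by -0.62 ± 0.08. Bmp2 did not pass without SP-C+ replicates 1, 2 and 3 (adjusted p = 0.0807). The list's median was 0.06 and its adjusted p 0.0412 (adjusted p = 0.369 with an estimated correlation), and it did not pass without SP-C+ replicate 1 (0.0889), SP-C+ replicate 2 (0.0702) or Axin2+ replicate 4 (0.0849), nor with either filter on dim genes, the Y-linked covariate or without SP-C+ replicates 1, 2 and 3 (adjusted p = 0.0673 to 0.266). Lower genes numbered 2 without Axin2+ replicate 2, 3 or 5.

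Notch and FGF lists did not pass with camera, although the FGF list passed with fry (adjusted p = 0.0160, direction down). In the Notch list 3 of 23 genes were higher and 4 lower, or 3 and 6 adjusted over the list alone (median -0.09, adjusted p = 0.431). Lfng, a glycosyltransferase of Notch receptors, rose by 1.07 ± 0.11 and Maml2, a coactivator, by 0.52 ± 0.13. The ligand genes Dll4 and Jag1 were lower by -0.73 ± 0.14 and -0.59 ± 0.13. Without SP-C+ replicates 4 and 5 the lower genes numbered 8, and without replicates 1, 2 and 3 Maml2 and Jag1 did not pass (adjusted p = 0.250 and 0.166). In the FGF list 1 of 15 was higher and 3 were lower, or 2 and 5 adjusted over the list alone (median -0.14, adjusted p = 0.187). Dusp4, a feedback phosphatase gene, was lower by -0.96 ± 0.12. Etv1, at -0.53 ± 0.14, lost its call without Axin2+ replicate 3 (adjusted p = 0.0557), and Fgfr3, at 0.46 ± 0.14, lost its call in 6 of 10 fits without 1 array (adjusted p up to 0.0938, without Axin2+ replicate 3).

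Of lung epithelial and progenitor transcription factors and keratins, 3 of 25 were higher and 3 lower, also adjusted over the list alone (median 0.00, adjusted p = 0.431). Krt19, a simple epithelial keratin, rose by 0.85 ± 0.18 and Mycn by 0.71 ± 0.10, while Sox9 and Elf5, genes of embryonic lung tips, were lower by -0.48 ± 0.09 and -0.46 ± 0.07. Higher genes numbered 6 without SP-C+ replicates 4 and 5.

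Interferon response genes rose in the same arrays as AEC1 (median 2.27) and ciliated cell markers (2.16), with 10 of 21 higher and 0 lower, also adjusted over the list alone. The median was 0.34 and the adjusted p 7.37e-07 (adjusted p = 0.148 with an estimated correlation). Ifit2 and Oasl2, both induced by type I interferon, rose by 2.41 ± 0.18 and 2.04 ± 0.27. Among the 10 list genes above the 50th percentile 4 were higher, with a median of 0.11.

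Of 14 MHC class II and antigen presentation genes, 7 were higher and 0 lower (8 and 0 adjusted over the list alone), with a median of 0.45, in the same arrays as AEC1 (median 2.27) and ciliated cell markers (2.16). H2-Ab1 and H2-Eb1, the beta chains of the class II A and E molecules, rose by 2.20 ± 0.44 and 2.20 ± 0.30. The adjusted p was 2.12e-06, and the call was lost with an estimated correlation (adjusted p = 0.185). H2-Ea, the alpha chain that pairs with the H2-Eb1 product and was not a member of the list, was lower by -2.17 ± 0.43 (adjusted p = 0.00365). It lay between 5.08 and 5.61 in Axin2+ arrays and spread from 6.12 to 9.16 in SP-C+ arrays. List means of SP-C+ replicates 4 and 5 were 8.72 and 8.69, against 7.96 to 8.06 in replicates 1, 2 and 3. Without replicates 1, 2 and 3, 2 genes passed (median 0.28), and without replicates 4 and 5, 11 did (median 0.67).

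Of 28 leukocyte markers 4 lay above the median gene in SP-C+ arrays, 1 was higher and 1 lower (1 and 0 adjusted over the list alone). The higher one was Csf1r, the receptor gene for macrophage colony-stimulating factor (2.50 ± 0.15). The lower one, Mrc1, was at -0.42 ± 0.13, a call that ended in 8 of 10 fits without 1 array (adjusted p up to 0.116, without Axin2+ replicate 1). The list median was -0.25 and its adjusted p 0.0386 (adjusted p = 0.474 with an estimated correlation), with 0.110 without SP-C+ replicate 1, 0.0919 without Axin2+ replicate 4 and 0.0549 without SP-C+ replicate 5. It also did not pass with either filter on dim genes or without SP-C+ replicates 4 and 5 (adjusted p = 0.0776 to 0.827), nor with fry (adjusted p = 0.0906).

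Of 26 endothelial markers 0 were higher and 1 was lower (0 adjusted over the list alone), Car4, a carbonic anhydrase, at -0.58 ± 0.18, a call lost in 8 of 10 fits without 1 array (adjusted p up to 0.0979, without Axin2+ replicate 2). The median was -0.25 and the adjusted p 0.137. The list mean was 7.25 in SP-C+ replicate 1 and 6.63 in replicate 3, against 6.11 to 6.31 in the other SP-C+ arrays and 6.16 to 6.38 in Axin2+ arrays. Without SP-C+ replicate 1 the median was -0.06. Without SP-C+ replicates 4 and 5, 7 members were lower and the list passed (median -0.42, adjusted p = 4.38e-04); it also passed without replicate 4 (0.0240) or 5 (0.0275) alone and with the replicate number as a block (0.0454). Without replicates 1, 2 and 3 it turned to 0.093 with an adjusted p of 0.0356.

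Of 33 mesenchymal markers 2 were higher and 5 lower, also adjusted over the list alone. Fbln5, an elastic fibre gene, rose by 3.59 ± 0.19 and Msln, mesothelin, by 3.12 ± 0.23. Col6a2, a collagen VI chain, was lower by -0.63 ± 0.10. Tgfbi was at -0.66 ± 0.21, a call lost in 8 of 10 fits without 1 array (adjusted p up to 0.109, without Axin2+ replicate 3). The median was -0.07 and the mean 0.12, which differ in sign, and the adjusted p was 0.973 (direction up). Higher genes numbered 4 without SP-C+ replicate 1 and 6 without SP-C+ replicates 1, 2 and 3. Of 10 measured erythroid genes 1 was higher and 1 lower, also adjusted over the list alone (median -0.10, adjusted p = 0.431 with camera). The erythroid list passed with fry (adjusted p = 0.0109, direction down). Car2, which epithelium also expresses, was at 0.42 ± 0.12 and Epb42, a red cell membrane gene, at -0.39 ± 0.11, and these calls were lost in 4 and 7 of 10 fits without 1 array (adjusted p up to 0.0629 without Axin2+ replicate 2 and 0.0871 without Axin2+ replicate 3).

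Immediate-early and heat-shock genes, which cell sorting can induce, did not shift: 4 of 30 were higher and 2 lower, also adjusted over the list alone (median 0.00, adjusted p = 0.651). The chaperone genes Hsph1 and Hspa1a rose by 1.28 ± 0.23 and 0.77 ± 0.12, and the chemokine gene Cxcl1 was lower by -0.92 ± 0.16. Higher genes numbered 2 without SP-C+ replicate 4 or 5 and without Axin2+ replicate 3, 4 or 5. Egr2, at -0.41 ± 0.12, lost its call in 6 of 10 fits without 1 array (adjusted p up to 0.0933, without Axin2+ replicate 2). Oxidative phosphorylation genes (0 of 38 higher, 1 lower, median 0.06, adjusted p = 0.135) and cytosolic ribosomal protein genes (0 of 31 higher, 2 lower, median -0.09, adjusted p = 0.246) did not pass, and adjusted over the list alone neither had a called member. Without SP-C+ replicates 1, 2 and 3 the oxidative phosphorylation list passed (adjusted p = 0.0260). The ribosomal protein list passed with fry (adjusted p = 0.0120, direction down). The lower members were Uqcrfs1 (-0.27 ± 0.08), Rpl5 (-0.54 ± 0.17) and Rps9 (-0.24 ± 0.07), whose calls were lost in 8, 7 and 6 of 10 fits without 1 array (adjusted p up to 0.106 without Axin2+ replicate 4, 0.102 without SP-C+ replicate 3 and 0.0679 without Axin2+ replicate 2).

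In all, 12 of 23 lists passed with the preset correlation, 9 higher and 3 lower. With a correlation estimated from the data 4 passed: AEC1, ciliated cell, club cell, and Hippo and YAP response genes.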

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

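Tests of other epithelial cells, of leukocytes and of shared class II regulation were chosen after the results were seen; those of array scaling, sex and the H2 region were written down before their own results were seen, the last 2 only after the main results were. Of 214 sets of 5 values tested for a sample far from the others, 8 had one, against 10.7 expected if chance marks 1 in 20.

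In each of 4 genes described here 1 array stood apart. P4ha3 measured 10.2 in Axin2+ replicate 3 and 9.43 to 9.57 in the other 4. Npffr2 was at 7.09 in Axin2+ replicate 4 against 5.59 to 5.97. Oasl2 was at 8.28 in Axin2+ replicate 5 against 6.61 to 6.90, and the mean of the interferon list was also highest there, 7.07 against 6.67 to 6.77. H2-Eb1 was at 9.48 in SP-C+ replicate 4 against 7.69 to 7.91. The AEC1 list mean was 9.47 in SP-C+ replicate 1 against 8.90 to 9.02. The mean of the sex-linked genes was 5.72 in SP-C+ replicate 4 against 7.44 to 7.53 in the other SP-C+ arrays. Among the 17824 probe sets without a single gene symbol, 409 were higher and 380 lower in Axin2+ arrays in limma's fit over all probe sets.

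AEC1, ciliated and, in part, club cell genes were higher in Axin2+ arrays, while 9 of 30 AEC2 markers were lower, a list call lost with an estimated correlation (adjusted p = 0.369). The lowest AEC1 median under the 2 other scalings was 2.24. Both started from values that the authors had already normalized, and they do not undo that step. They show that the rise survives further scaling, but cannot decide on the authors' own scaling. The sex of the animals is argued against, since with a Y-linked covariate the AEC1 median was 2.21. Ciliated cell genes, of which 5 of 26 lay above the median gene in SP-C+ arrays, rose as a set (median 2.16), which is consistent with other epithelial cells in the Axin2+ sort: its gate asked for EpCAM, which airway cells also carry, and excluded only endothelial cells and leukocytes. For AEC1 genes, 24 of 25 already above the median gene in SP-C+ arrays, the AEC2 median of -0.19 does not decide, because RNA pooled from many cells gives the same values for a mixture with AEC1s and for AEC2s that express AEC1 genes, which cannot be told apart. A difference in state between Wnt-responsive and other AEC2s stays open and was not tested apart from the gate.

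Of 14 MHC class II and antigen presentation genes 7 were higher in Axin2+ arrays, but 2 without SP-C+ replicates 1, 2 and 3, the list lost its call with an estimated correlation (adjusted p = 0.185), and H2-Ea was lower. Stronger shared regulation alone does not account for H2-Ea, which moved by -2.17. It stays open for the other class II genes, because the level of H2-Ea can also follow the haplotype. Ciita, the class II transactivator gene, was at 0.29 and did not pass (adjusted p = 0.453 in limma), which does not decide. Leukocytes in the Axin2+ sort, whose gate excluded CD45, stay open: the leukocyte list median was -0.25, Ptprc, which encodes CD45, was at -0.30 (adjusted p = 0.221) and Cd68 at -0.66 (adjusted p = 0.0529), but Csf1r rose by 2.50, and no leukocyte sample shows how far the others should rise beside class II genes. Some H2 haplotypes, that of C57BL/6 among them, carry an inactive H2-Ea, so unequal haplotypes in the mixed background may contribute. Called genes did not crowd the region enough to decide: 11 of 41 genes around H2-Ea, percentile 83.4 of 21164 windows, whose median was 7.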

How the results depend on the processing

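The Y-linked covariate, the fits without several SP-C+ arrays and the other Axin2 probe set were chosen after the main results were seen. Over the settings fixed beforehand that keep the threshold, called genes numbered between 2974 (without Axin2+ replicate 3) and 4303 (median centring). At an adjusted p under 0.01, 2249 genes passed, 919 of them lower, and with at least a 1.5-fold difference 1600 passed, 1141 higher and 459 lower; these counts are smaller by construction. With the Y-linked covariate 3155 genes passed, without SP-C+ replicates 4 and 5 4300, and without SP-C+ replicates 1, 2 and 3 2839. With an estimated correlation 4 lists passed, 4 higher and 0 lower, and with fry 5 were lower; both differ from the main test in how they treat correlation or other genes. The other Axin2 probe set kept its direction (-0.32); adjusted over all probe sets, not over genes, its p was 0.0557 and that of the main probe set 0.00112. The leukocyte list, with a median of -0.28 among its 4 genes above the 50th percentile, changed camera direction there (adjusted p = 0.827), and the endothelial list turned to 0.093 without SP-C+ replicates 1, 2 and 3; the cause was not tested. Over 23 lists and all alternatives 488 values kept their side of the threshold, 30 lost the call, 9 gained it and 2 reversed. A change of direction was not counted where a list passed in neither fit, so some of the 488 may have changed direction. Over 81 named genes 1564 values kept direction and side of the threshold, 131 lost the call, in 23 genes, and 0 reversed.

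No pairing by replicate number was seen: deviations from the group means of same-numbered arrays correlated at -0.05, -0.07, 0.01, -0.23 and -0.18. These values do not exclude a shared litter, sort or array batch. With the replicate number as a block 2979 genes passed, 2915 of them shared with the fit without it.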

Other observations

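Gene families named by shared symbol stems, the genes picked from them and the tests on Axin2 were chosen after the results were seen; the tests of neighbouring genes and of other splits were written down before their own results were seen.

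Beyond the fixed lists, axonemal genes rose widely. Of 32 Cfap genes, which encode cilia and flagella proteins, 27 were higher and 0 lower in Axin2+ arrays, with a median of 1.38. Cfap206 led with 3.85 ± 0.12 SE, and only 1 of the 32 stood in a fixed list. Of 11 Dnah genes, dynein heavy chains, 8 were higher and 0 lower, Dnah6 by 3.21 ± 0.12, and 3 of the 11 stood in a fixed list. Among 14 Ift genes of intraflagellar transport 8 were higher and 1 lower. Camera gave adjusted p-values of 1.06e-29, 1.09e-10 and 7.75e-04 over 319 families, and 0.168, 0.168 and 0.989 with an estimated correlation.

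Some integrin beta genes were higher and some fatty acid binding protein genes lower. Itgb6, the partner of the integrin alpha v chain that activates latent TGF-beta, was higher by 3.19 ± 0.12, with Itgb3, Itgb4 and Itgb5 at 2.21 ± 0.16, 1.55 ± 0.16 and 1.18 ± 0.12. The family of 12 had 4 higher and 0 lower members and did not pass (adjusted p = 0.0527). Of 9 Fabp genes 4 were lower and 0 higher (adjusted p = 0.0130, and 0.404 with an estimated correlation). These were Fabp12 (-1.31 ± 0.11), Fabp4 (-1.09 ± 0.22), Fabp9 (-0.86 ± 0.12) and Fabp5 (-0.45 ± 0.08).

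Axin2 was lower in the arrays labelled Axin2+. A single wrong label is argued against, since 0 arrays lay on the other group's side of the midpoint for Axin2 or the first principal component. So is an exchange of the group labels, since ciliated cell genes, which an Sftpc driver should not trace, had a median of 2.16 in favour of the arrays labelled Axin2+. Fewer transcripts from the engineered Axin2 allele may account for the fall, as the other probe set also lay lower (-0.32), but where the allele interrupts the transcript is not given in the sources used here. Lower Wnt target expression as a whole was not found: the other 22 targets went both ways (median -0.11, camera p = 0.998, a model-based rather than exact value). This test does not exclude a fall of some targets.

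Of the 41 genes around Axin2, 9 were called (percentile 64.1 of all such windows), and of the 41 around Sftpc, 2 were called (percentile 4.72).

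No other split that was tried gave as many called genes. Of the 126 splits of the arrays into 5 and 5, 100 were run. Only the real one gave as many as 3894, and the highest other split gave 1. The splits treat the arrays as independent samples, which no label states.

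Xist and Y-linked genes did not split the arrays by group. Xist was between 11.79 and 12.90 in SP-C+ replicates 1 and 4 and Axin2+ replicates 1, 2, 3 and 5, and between 5.98 and 6.58 in the other 4. Y-linked Eif2s3y was at 7.13 in SP-C+ replicate 1 and 9.11 in Axin2+ replicate 2, beside Xist at 12.48 and 11.79, so these 2 arrays carried both Xist and Y-linked RNA.

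On the second principal component (11.2% of the variance) SP-C+ replicates 4 and 5 lay at -24.0 and -23.3 and replicates 1, 2 and 3 between 10.1 and 18.4, with Axin2+ arrays between -8.77 and 9.49. A probe set shared by Cd74 and a microRNA gene was at 0.56 (adjusted p = 0.112 in limma over all probe sets).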
